A study of Mus musculus with 8 samples.

How the data were processed

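H3K36me3 ChIP-seq and input libraries from mouse embryonic stem cells with inducible Setd2 knockdown were used, 2 replicates of each in control and knockdown cells, grouped by the treatment, antibody and genotype given in the labels. Per the labels' protocols, cells were cultured in medium with 1 µM PD0325901, 3 µM CHIR99021 and 1000 U/ml LIF, chromatin was sonicated, and complexes were isolated with an H3K36me3 antibody. The labels number the replicates but do not say whether they came from separate cultures. Per the submitters' processing notes, FastQC 0.11.5 and Bowtie 1.1.2 were used with the mouse genome build mm10. How reads with several matches in the genome were treated is not given in the sources used here.

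Per the file headers, the authors called peaks with MACS 1.4.2 on the merged alignments of replicates 1 and 2 against the merged inputs, with a p cutoff of 1e-05, an effective genome size of 1.87e+09, a tag size of 50 bp, a band width of 300 bp, model folds of 10 to 30 and a fragment length of 294 bp. Per the file headers, 1 tag was kept per position, the larger of the ChIP and input data sets was scaled to the smaller, and local background was taken over 1000 and 10000 bp. Each condition thus has 1 deposited peak table. For each peak it gives the count of tags as the authors' caller counted them, not normalized. It also gives a deposited score, which is minus 10 times the log10 of the caller's p-value, a fold enrichment, which is the authors' ratio of ChIP to local background, and an empirical FDR in percent as deposited by the authors. Scores, folds and FDR values are the authors' own and were used only to describe, rank or filter peaks within their list. The deposited BED files hold the same peaks with an FDR of 5% or less, 30595 in control and 2961 in knockdown, and their fold column equals that of the tables within 0.01. The peaks they leave out are high-scoring ones: 39 in control with scores of at least 1745, and 79 in knockdown with scores of at least 272. Lists called on merged replicates allow no comparison of replicates, so no p-value was computed between conditions.

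Depth was read from the file headers. ChIP libraries held 42509111 tags in control and 38670982 in knockdown, and duplicate removal took 14.7% and 23.9% of them. Inputs held 39607031 and 37471825 tags, of which 35134297 and 33403964 were kept. Shares are given with exact Clopper-Pearson 95% binomial intervals, which cover counting error only, since tags and neighbouring peaks are not independent.

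Genes were taken from a RefSeq gene table of assembly GRCm38.p6, the build of the peak coordinates. The 21887 protein-coding genes on chromosomes 1 to 19, X and Y were used. The table gives gene start and end and no strand, exons or transcript starts. The planned profile from the 5' to the 3' end was therefore folded from gene ends to the middle, and the planned classes by transcript start, exon and intron were replaced by protein-coding gene, other gene and intergenic, with the distance to the nearest gene end in place of that to the transcript start. A gene had a peak when the midpoint of at least 1 peak lay between its start and end. A small or overlapping gene can thus be covered without holding a midpoint, and overlapping genes share peaks. The covered share is the percent of gene length under peaks. Peaks overlapped when they shared at least 1 bp, and the chance level was described by 1000 circular shifts of the knockdown peaks within each chromosome.

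The overlapped shares by place in or outside protein-coding genes were chosen after the data had been seen. The groups, planned comparisons, 32 gene lists, main alternatives and the rule for named genes were fixed before the data were examined. The rule names the H3K36 methyltransferases, overlapping genes included. Its rankings cover protein-coding genes that overlap no other and have no Gm or Rik symbol. Among these it names the 10 with the most control-covered base pairs and no knockdown peak and the 10 with the most knockdown-covered base pairs. It also names the 5 with the most knockdown-covered base pairs and no control peak. From each list it names the 2 members with the highest control-covered and the 2 with the highest knockdown-covered share, overlapping genes included. It also names the 5 highest-scoring peaks of each list without overlap in the other. Some genes that the rule names are not reported here. The lists comprise H3K36 methyltransferases, demethylases and reader proteins, m6A factors, naive and formative or primed pluripotency, 2-cell-like, primitive endoderm, mesoderm, neuroectoderm, trophoblast, fibroblast, hepatocyte, muscle, blood and synapse markers, olfactory receptors, histones, Zfp genes, ribosomal proteins, proteasome, complex I, chaperonin CCT, RNA polymerase II, elongation, splicing and translation factors, glycolysis, DNA replication, DNA repair, FGF and MAPK signalling and imprinted genes. Each list's kept share was set against 10000 random lists of the same size matched on deciles of control-covered share.

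The background implied by each peak's score was found by solving the Poisson tail for the mean that gives the printed score at the peak's tag count, and divided by the mean tag number that the genome-wide density gives over the peak's length. Overlap and coverage code was tested on simulated data. Of 200 control peaks planted with a shift among as many peaks placed in gaps, 200 were recovered as overlapping, and 200 of 200 simulated backgrounds were recovered within 1%. Counts also equalled those of bedtools 2.31.1. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9. The alternatives were a score of at least 100, an FDR of 1% or less, peaks within 3 kb joined, chromosomes 1 to 19 alone, the BED files, overlap of 50% of a peak or of both, a control list cut to the 3040 top-scoring peaks, other rules for genes with a peak, genes of 20 kb or longer, 2 kb around gene ends and unmatched random lists.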

Results

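H3K36me3, the trimethylated form of lysine 36 of histone H3 that marks the bodies of transcribed genes, was profiled by ChIP-seq in mouse embryonic stem cells. The cells grew without feeders as spheres in 2i medium with LIF, a combination of a MEK inhibitor, a GSK3 inhibitor and leukaemia inhibitory factor that holds them in the naive state. They carried a doxycycline-inducible knockdown of Setd2, the main H3K36 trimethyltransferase of mammalian cells. Control cells received no doxycycline, and knockdown cells received 1 µg/ml for 4 days. The 8 libraries form 4 groups of 2 replicates, H3K36me3 ChIP and input in each condition. The authors called peaks over both replicates merged, so each condition is represented by 1 peak list. There is therefore no replicate spread and no test between the conditions, and all intervals given are exact binomial 95% intervals that cover counting error only. The merged ChIP libraries held 42509111 tags in control and 38670982 in knockdown, of which 36244210 and 29416169 were kept by the caller after removal of duplicates. The merged inputs kept 35134297 and 33403964.

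The first comparison asked how much of the H3K36me3 landscape was left after Setd2 knockdown. Most of it was no longer called. The control list held 30634 peaks covering 110.7 Mb and the knockdown list 3040 peaks covering 5.67 Mb, so that peaks were 10.1 times and covered length 19.5 times lower after knockdown. Peaks held 16.3% (16.3 to 16.4) of all kept tags in control and 0.755% (0.752 to 0.758) in knockdown. The remaining peaks were also shorter, with a median of 1594 bp against 2451 bp. Relative to the mean density of kept tags over the genome, which takes the unequal depth into account, peaks held 2.49 times as many tags per kb in knockdown and 2.76 times in control. Each value covers its own list, where every peak had to pass the caller's threshold. These values therefore do not compare the mark at the same sites. Peaks above 10 kb numbered 1527 in control and 5 in knockdown. On the 19 autosomes the control list exceeded the knockdown list by 7.76 times (chromosome 13) to 14.1 times (chromosome 12). With only peaks of caller score 100 or more in both lists the ratio of peak numbers was 21.7.

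Setd2 itself, on chromosome 9 at 110532500 to 110618633 (mm10), carried 11 control peaks over 40.1% of its length and no knockdown peak. This describes the chromatin of the gene and does not measure its transcript or protein. The other H3K36 methyltransferase genes lost most or all of their peaks too. Ash1l (14 control peaks), Nsd3 (6), Smyd2 (4) and Nsd2 (1) had no knockdown peak, and only Nsd1 had 1, over 1.54% of a gene that was covered to 34.4% in control.

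The second comparison asked whether the knockdown list was a remnant of the control list. It largely was. Of the 3040 knockdown peaks, 2226 (73.2%, 71.6 to 74.8) overlapped a control peak by at least 1 bp, against a median of 6.51% when the knockdown peaks were shifted along their chromosomes 1000 times. In the other direction 1998 of 30634 control peaks (6.52%, 6.25 to 6.80) were overlapped by a knockdown peak, with a shifted median of 0.655%, and no shift reached either observed value. In length, 4.13 Mb of control peaks, or 3.73%, stayed covered. Control peaks that were overlapped were longer, higher-scoring and denser within their own list. A longer peak is more easily overlapped by 1 bp, and the caller score varied with length, so neither measures strength alone. By tags per kb the overlapped share rose from 2.42% (1.90 to 3.02) in the lowest decile to 24.2% (22.7 to 25.8) in the highest. The median length of overlapped control peaks was 3647 bp against 2395 bp for those that were not. The overlapped share rose from 2.48% (1.96 to 3.09) in the lowest decile of caller score to 18.1% (16.7 to 19.5) in the highest. The control peaks with the highest scores and no knockdown overlap lay over Usp19, Kif2c, Fabp3, Amotl2 and Sesn2, with caller folds over background of 7.24 to 9.78 in the authors' table. The strongest of them spanned 11062 bp of chromosome 9 from 108492373 to 108503434 at Usp19, a deubiquitinase gene. The highest-scoring knockdown peaks without control overlap lay over Zfp982 (2 peaks), Son and Top2a and in an intergenic stretch of chromosome 17 from 93477800 to 93481282. The overlap shares depended on the rule: when each peak had to cover at least 50% of the other, 29.9% of knockdown peaks and 2.97% of control peaks qualified. Against only the 3040 top-scoring control peaks, 21.6% of knockdown peaks and 18.2% of those control peaks were overlapped.

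The third comparison concerned where in the genome peaks were no longer called. Control peaks inside protein-coding genes were overlapped by a knockdown peak far less often than those between genes. This contrast was chosen after the data had been seen. Input signal and reads with several matches were not examined by place, so its cause was not tested. In control, 25627 peaks (83.7%, 83.2 to 84.1) had their midpoint in a protein-coding gene and 4153 (13.6%, 13.2 to 13.9) were intergenic. In knockdown, 1386 (45.6%, 43.8 to 47.4) were in protein-coding genes, which span 37.9% of the genome, and 1395 (45.9%, 44.1 to 47.7) were intergenic. Of the control peaks in protein-coding genes 3.85% (3.62 to 4.09) were overlapped after knockdown, compared with 20.7% (19.5 to 21.9) of the intergenic ones and 17.9% (15.4 to 20.7) of those in other annotated genes, such as non-coding genes and pseudogenes. The intergenic share was 5.38 times the genic share although the intergenic control peaks were shorter and less dense. It was higher in 10 of 10 deciles of tags per kb, from 9.34% against 0.665% in the sparsest to 55.3% against 21.7% in the densest. Of the 814 knockdown peaks without a control counterpart, 455 (55.9%, 52.4 to 59.3) were intergenic. Peaks within 1 kb of an end of a protein-coding gene made up 6.86% (6.58 to 7.15) of control and 3.98% (3.31 to 4.74) of knockdown peaks.

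**Figure D1:**
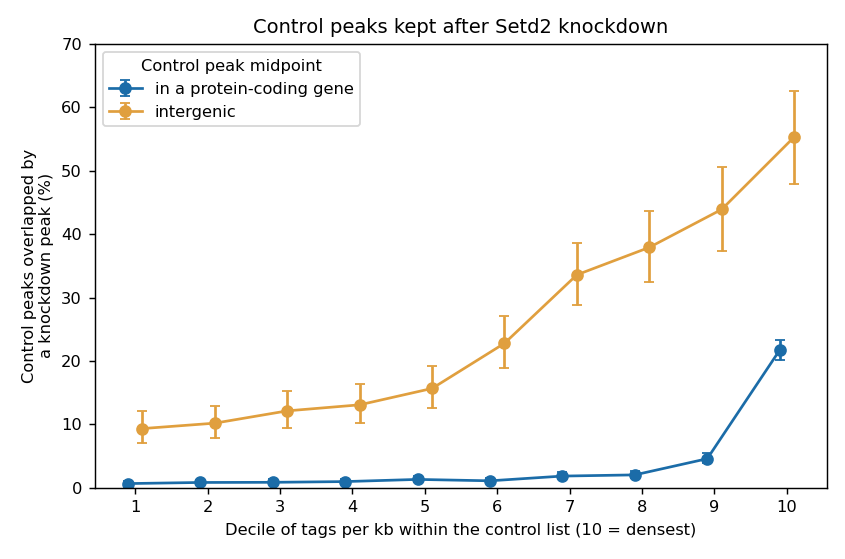
Share of control peaks overlapped by a knockdown peak (vertical axis, percent) in each decile of tags per kb within the control list (horizontal axis, 10 densest), for peaks with their midpoint in a protein-coding gene (blue) and intergenic peaks (orange); bars are exact 95% binomial intervals. The intergenic share lies above the genic share in all 10 deciles and reaches 55.3% against 21.7% in the densest.

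The position of the control peaks along genes depended on how genes were averaged. Over the 16853 protein-coding genes of 5 kb or longer, each cut into 10 equal bins that were folded from both ends to the middle, the mean covered share per gene rose from 16.1% in the outermost bins to 22.0% in the middle, and was 11.3% in the 1 kb next to the gene. In knockdown these values were 0.469%, 0.624% and 0.305%. Covered base pairs were also summed over genes, which lets long genes dominate. The covered share was then 9.29% in the outermost bins and 9.16% in the middle in control, and 0.254% and 0.249% in knockdown. The flanking 1 kb has the same length for every gene. Its 11.3% and 0.305% are therefore not weighted by gene length and cannot be set against these summed shares. Over genes of 20 kb or longer the summed share in control fell from 8.53% in the outermost bins to 7.39% in the middle. The direction of transcription was not used here, so the 5' and 3' sides of genes were not separated.

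At the level of genes, 9016 of 21887 protein-coding genes (41.2%) had a control peak and 1084 (4.95%) a knockdown peak. Both lists marked 956 genes, 10.6% (9.98 to 11.3) of those marked in control, where independent lists of these sizes would share 447. A further 8060 genes had a peak in control alone and 128 in knockdown alone. The median gene with a control peak was covered over 37.9% of its length (quartiles 13.9% and 65.0%). Genes covered over at least 50% of their length fell from 3718 to 36. The 956 genes with both had a median coverage of 47.5% in control and 5.84% in knockdown. Requiring coverage of at least 10% of the gene left 7796 genes in control and 375 in knockdown. Across the alternatives the kept share ranged from 2.29% (FDR of 1% or less) to 19.4% (the 3040 top-scoring control peaks), and the genes with a knockdown peak alone from 23 (coverage of at least 10%) to 605 (the top-scoring control peaks).

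The next rankings cover only protein-coding genes that overlap no other and have no Gm or Rik symbol. Among these, the longest marked territories without any knockdown peak were in large genes. Cit, which encodes citron kinase of cytokinesis, had 114240 bp under 23 control peaks, and Tns3, a focal adhesion gene, had 110775 bp. Smarcc1, which encodes a subunit of the BAF remodelling complex, had 79407 bp, Brwd1, a bromodomain gene covered over 85.5% of its length, 77491 bp, and Ep400, a chromatin remodeller gene, 73735 bp. Drosha (78794 bp) encodes the nuclease that starts microRNA processing, Nup210 (74047 bp) belongs to the nuclear pore, and Helz (72589 bp) is an RNA helicase gene. They were also among the 10 genes in this ranking with the most control-covered sequence and no knockdown peak.

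Of the 10 genes with the most sequence under knockdown peaks, among those that overlap no other gene and have no Gm or Rik symbol, 3 were zinc finger genes. Zfp936, a zinc finger gene on chromosome 7 at 43114166 to 43192109, was covered over 48.2% of its length in control and 45.5% in knockdown, with 7 and 9 peaks. Zfp982, in a zinc finger cluster of chromosome 4 at 147443114 to 147516064, was covered over 8.86% in control and 40.4% in knockdown. Agrn, which encodes the proteoglycan agrin, went from 88.5% to 55.8%, and Prpf8, the core U5 component of the spliceosome, from 92.9% to 58.1%. Trim24 (66.2% to 14.2%), Cep57l1 (57.3% to 19.2%), Zfp462 (33.8% to 11.7%) and Pakap (11.3% to 2.53%) lost a larger part. The potassium channel gene Kcng2 (13.3% and 17.7%) and the perlecan gene Hspg2 (9.01% and 11.5%) had low coverage in both lists.

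Genes with a knockdown peak and no control peak were ranked within the same set, which overlaps no other gene. Top2a (9089 bp, 29.1% of its length), which encodes the topoisomerase of mitotic chromosomes, had the most knockdown-covered base pairs. Next came Dync1h1 (6512 bp, 9.93%), the cytoplasmic dynein heavy chain, and Cct3 (5265 bp, 21.4%), a chaperonin subunit. Dhx9 (3475 bp, 10.9%), an RNA helicase gene, and Rest (3216 bp, 15.4%), a repressor of neuronal genes, followed. None of these 5 had a base pair under a control peak. In the control list the background implied by the caller's own scores was 1.06 times the genome mean for peaks up to 8 kb and 2.74 times for peaks above 20 kb, a limit on how far an empty control interval in a long gene can be read.

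**Figure D2:**
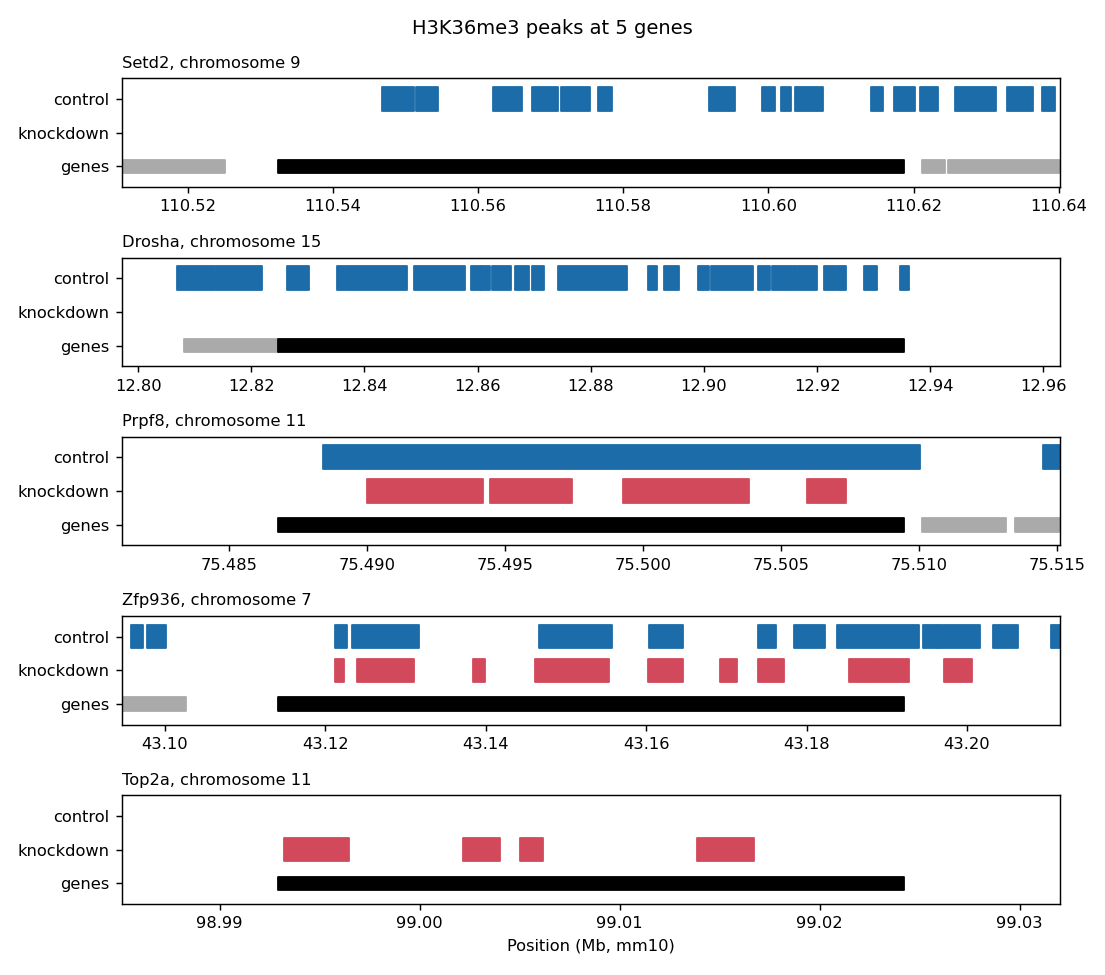
Maps of H3K36me3 peaks in control (blue) and Setd2 knockdown (red) over 5 genes (black) and neighbouring protein-coding genes (grey), with the position in Mb on mm10 on the horizontal axis. Setd2 and Drosha have control peaks alone, Prpf8 keeps 4 knockdown peaks under 1 long control domain, Zfp936 has 7 control and 9 knockdown peaks counted by midpoint, and Top2a has 4 knockdown peaks and no control peak.

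The fourth comparison asked which groups of genes carried the mark and which kept it. For each of 32 gene lists the percentile of the kept share, meaning the share of members with a control peak that also had a knockdown peak, was taken among 10000 random gene lists matched on control-covered share. These percentiles describe the 2 peak lists and are not p-values. The random lists were not matched on gene length or tags per kb, so a high percentile does not set these aside. Among the 26 lists with enough marked members, 6 had a kept share above that of all but the highest 2.5% of random lists.

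Naive pluripotency genes were widely marked in control, 28 of 32, and 9 of the 28 (32.1%, 15.9 to 52.4) kept a peak, at percentile 99.5. Fgf4, which encodes the autocrine growth factor of these cells, was covered over 100% and Nanog, a core pluripotency factor, over 98.3% in control, and neither had a knockdown peak. Trim28, the corepressor recruited by KRAB zinc finger proteins, stayed covered over 81.0% of its length against 92.0% in control. All other kept members had far lower knockdown coverage, from 1.54% (Tet2, 32.6% in control) to 16.9% (Dnmt3l, 34.3% in control). Klf2, a naive-state transcription factor, had 41.3% against 95.1%. Its control peak had its midpoint outside the gene, so Klf2 is not among the 9. Formative and primed pluripotency genes had a control peak in 6 of 13 cases, and 2 of the 6 (33.3%, 4.33 to 77.7; percentile 96.2) kept one. These were Dnmt3b (45.8% to 5.08%), a de novo DNA methyltransferase, and Lef1 (1.60% to 0.954%). Zic2 (59.4%) and Lefty2 (47.5%) had none.

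Chaperonin, translation, splicing and elongation genes had the 4 highest kept shares of the 26 lists. Of 32 marked splicing factor genes among 34, 13 (40.6%, 23.7 to 59.4; percentile 100) kept a peak, among them Hnrnpl (79.0% to 46.7%), while Snrnp200 (96.5%) and Sf3a3 (96.3%) lost theirs. Translation factors kept 9 of 19 among 20 genes (47.4%, 24.4 to 71.1; percentile 99.7). Eef2, the ribosomal translocase, was covered over 100% in control and 88.3% in knockdown and Eif4a2 over 97.49% and 61.7%, whereas Eif2s2 went from 100% to 0. The chaperonin CCT kept 5 of 7 among 8 genes (71.4%, 29.0 to 96.3; percentile 99.9), with Cct2 at 95.2% and 44.8% and Cct4 at 94.2% and 10.5%. Transcription elongation factors kept 8 of 23 among 24 genes (34.8%, 16.4 to 57.3; percentile 99.8), with Cdk9, the kinase of P-TEFb, at 84.7% and 21.6%, Ssrp1 at 79.4% and 14.2%, Supt5 at 87.1% and 6.27% and Nelfb at 93.3% and 0.

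Other groups of broadly used genes lay nearer to the random lists. Cytosolic ribosomal protein genes kept 17 of 57 among 84 (percentile 93.2), with Rpl3 (100% to 88.0%) and Rps3 (98.3% to 78.0%) high in both and Rpl41 and Rps26 going from 100% to 0. Proteasome genes kept 7 of 30 among 39 (percentile 92.7), with Psmc4 (89.97% to 19.1%), Psmd7 (82.8% to 18.5%), Psmc1 (91.5% to 9.15%) and Psmc6 (95.6% to 0). DNA replication genes kept 6 of 23 among 25 (percentile 89.3), with Cdt1 (89.9% to 63.5%), Lig1 (92.1% to 32.6%), Mcm5 (97.3% to 26.5%) and Mcm10 (94.4% to 0). Glycolysis genes kept 3 of 14 among 15 (percentile 79.99), with Pkm (82.9% to 27.6%), Eno1 (84.1% to 13.4%), and Gpi1 (94.4%) and Ldhb (90.04%) without a knockdown peak. DNA repair genes kept 3 of 21 (percentile 68.1), with Parp1 (86.6% to 17.3%), Xrcc5 (64.3% to 5.48%) and Msh6 (96.1% to 0). RNA polymerase II subunits kept 1 of 8 among 12 (percentile 59.7), Polr2a (65.3% to 16.3%), while Polr2e (87.2%) and Polr2f (73.2%) kept none. Complex I of the respiratory chain kept 0 of 26 among 37 genes (upper bound 13.2%; percentile 4.76), including Ndufa7 (81.8%) and Ndufv1 (80.9%).

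Among genes that write, erase or read the mark, kept shares lay within the range of the random lists, and 10.6% of all marked genes kept a peak. H3K36 demethylase genes kept 0 of 7 among 8 (percentile 25.3), with Riox1 (76.9%) and Kdm4b (44.5%) the most covered in control. Genes for H3K36me3 reader proteins kept 1 of 10 among 12 (percentile 35.1), Dnmt3b, while the mismatch repair gene Msh6 and Glyr1 (92.3%) kept none. The H3K36 methyltransferases, with 1 of 6, lay at percentile 77.9. The m6A RNA methylation genes kept 1 of 18 among 19 (percentile 29.0), Igf2bp1 (53.1% to 5.66%), whereas Alkbh5 (91.6%) and Ythdf1 (82.9%) kept none. FGF and MAPK signalling genes kept 2 of 18 among 24 (percentile 63.1), Nras (80.2% to 15.3%) and Etv5 (66.3% to 12.6%), and Map2k2 (87.2%) kept none. Imprinted genes kept 1 of 7 among 18 (percentile 70.6), Igf2r (54.4% to 3.10%).

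Over the 8 lists of other lineages and cell types with any control peak, 7.14% (blood cells) to 41.7% (trophoblast) of members had one, where 41.2% of all protein-coding genes did. Control peaks were found at 5 of 17 primitive endoderm genes, where Lama1 (53.3%) and Sparc (48.3%) had no knockdown peak and Lamc1 went from 25.3% to 1.78%. They were found at 4 of 13 mesoderm, 3 of 14 neuroectoderm and 5 of 12 trophoblast genes, none of which had a knockdown peak. The most covered members of these 3 lists in control were Gsc (54.1%) and Tbx6 (43.7%), each under a peak whose midpoint lay outside the gene, Sox1 (38.1%) and Nes (27.2%), and Krt18 (62.4%) and Tfap2c (58.5%). Fibroblast genes, which would mark feeder cells, had control peaks at 3 of 16, with Vim at 28.5% and Fn1 at 8.67% and 7.67%. Striated muscle genes had 4 of 14, with Ryr1 (19.4% to 0) and the very long Ttn (18.1% to 3.39%), blood cell genes 1 of 14 (Cd8a, 36.5%) and synapse genes 2 of 16 (Grin1, 56.7%, and Cntnap2, 0.0825%), with 1 knockdown peak at Grin2a (0.310%). No peak of either list had its midpoint in the 12 hepatocyte, 11 annotated 2-cell-like or 62 replication-dependent histone genes. A gene shorter than most peaks can be covered without holding a midpoint, so this does not show that such genes were uncovered. Of 1110 olfactory receptor genes 2 had a control peak, Olfr725 (37.6%) and Olfr91 (3.76%).

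**Figure D3:**
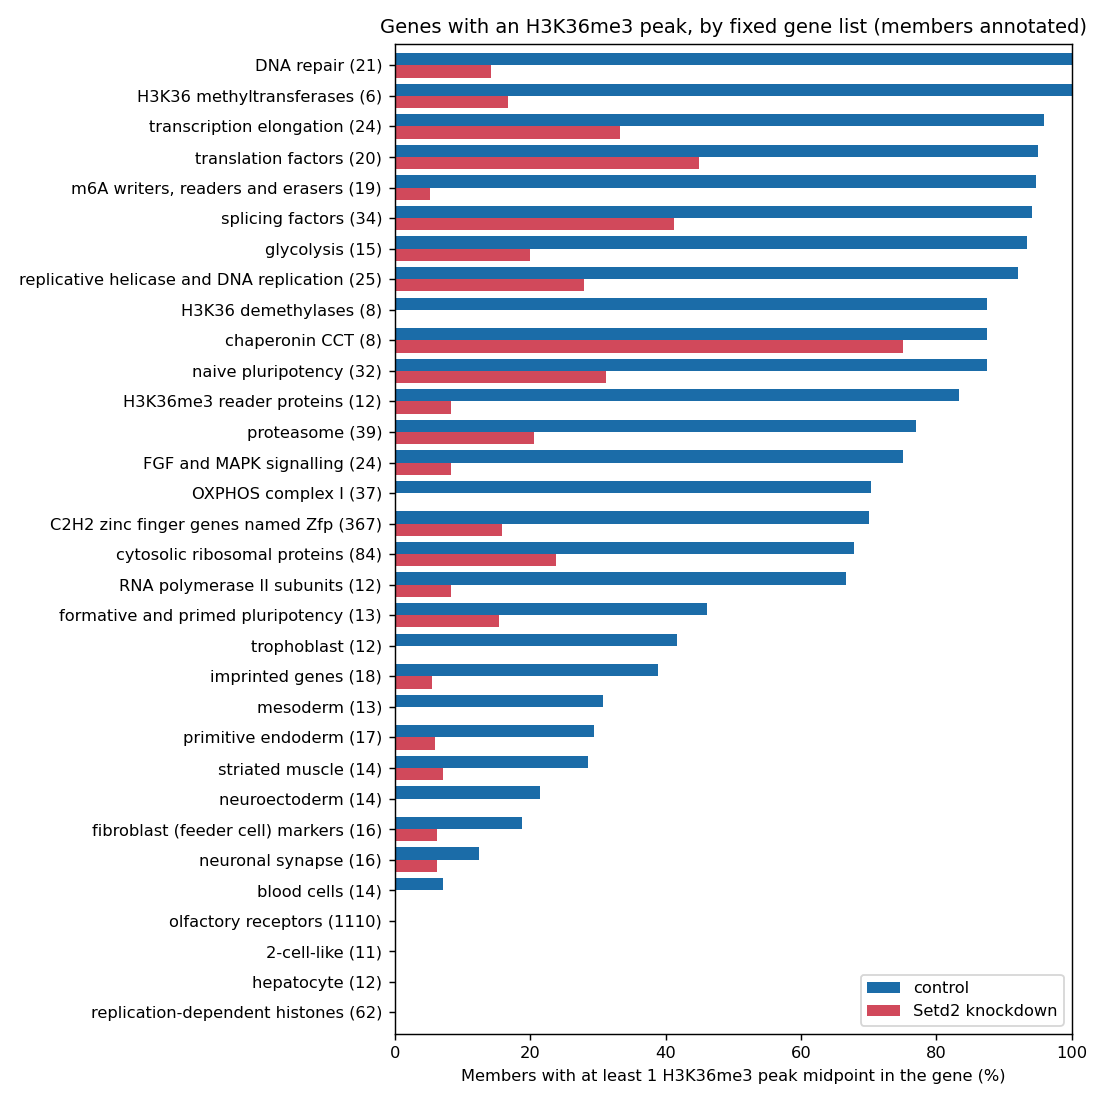
Percent of the annotated members of each of 32 gene lists (number of members in parentheses) with at least 1 H3K36me3 peak midpoint in the gene, in control (blue) and Setd2 knockdown (red). The knockdown bar is shorter wherever a control bar exists, and the chaperonin CCT has the longest knockdown bar, with 6 of 8 genes.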

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

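The settings limited to peaks of 8 kb or shorter, without chromosome 4 and with the profile averaged over genes, and the values by place in or outside protein-coding genes, were chosen after the data had been seen. With a caller score of 100 or more there were 19470 control and 899 knockdown peaks, ratios of 21.7 in number and 37.5 in length, overlapped shares of 3.56% of control and 82.3% of knockdown peaks, 370 genes with a knockdown peak, a kept share of genes of 4.38%, 37 genes with a knockdown peak alone, genic shares of 87.2% and 47.6%, and overlapped control peaks of 2.01% inside and 14.1% outside protein-coding genes. With an FDR of 1% or less these became 588 knockdown peaks, ratios of 51.8 and 145, overlapped shares of 1.06% and 55.3%, 251 genes, 2.29% kept, 47 with a knockdown peak alone, and 0.625% inside and 3.26% outside. That setting removed the strongest knockdown peaks, since in that list the FDR rose with the score (Spearman's rho 0.952 across peaks). Joining peaks within 3 kb gave 18637 control peaks, 10.1% of them overlapped, 78.9% genic, and 6.43% overlapped inside and 23.6% outside genes. Overlap of 50% of the peak gave 3.31% of control and 71.2% of knockdown peaks, and of both peaks 2.97% and 29.9%. The control list cut to the 3040 top-scoring peaks gave 18.2% and 21.6%, 2471 genes with a control peak, 19.4% of them kept and 605 genes with a knockdown peak alone. Coverage of 10% of the gene gave 375 genes with a knockdown peak, 4.52% kept and 23 with a knockdown peak alone. Peaks of 8 kb or shorter gave 5.52% and 54.2% overlapped, 9.04% of genes kept, 334 genes with a knockdown peak alone, 82.4% of control peaks genic and 2.45% overlapped inside genes. Peaks within 2 kb of a gene end were 13.0% of control and 9.64% of knockdown peaks. For other changes than these the cause was not tested. In each of these settings where both were computed the control list exceeded the knockdown list and the overlapped share was higher outside than inside protein-coding genes. The covered share in the middle over that at the ends of genes in control was 0.986 summed over genes and 1.36 averaged over them, so its direction depended on the averaging. Of the 26 lists with a kept share, 6 lay in the highest 2.5% with matched and 9 with unmatched random lists, the same 6 among them. Chromosomes 1 to 19 alone and leaving out chromosome 4, run on peak numbers, overlap, genes and place, moved none of these beyond its interval or 1.5 times, nor did the BED files for peak numbers and length, or any overlap with the gene and genes overlapping no other for the gene values. No paired analysis was possible because the peaks were called on merged replicates, and leaving out each replicate in turn was not run for the same reason. Depth limits the weakest peaks: knockdown ChIP kept 81.2% as many tags as control.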

Other observations

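The test of chance peaks among genes with a knockdown peak alone, and the count without tissue-restricted genes, were chosen after the result had been seen. Zinc finger genes named Zfp, many of which encode KRAB repressors of retroelements, were widely marked. Of 367, 257 had a control peak and 54 of these (21.0%, 16.2 to 26.5) also a knockdown peak, against a median of 8.95% in matched random lists. The knockdown peak could lie anywhere in the gene and need not overlap the control peak. Zfp982 counts as kept, although among its 4 knockdown peaks those of 6331 and 7976 bp had no control overlap. The most covered in control were Zfp110 (92.5%, with 8.71% in knockdown) and Zfp646 (91.9%, with none), and the most covered in knockdown were Zfp936 (45.5%) and Zfp982 (40.4%). On chromosome 4, 11 of 21 marked Zfp genes kept a peak, and on chromosome 7, 16 of 72.

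The X chromosome had few peaks in either condition. It held 124 control peaks, or 12.8 per 100 protein-coding genes, against 98.3 to 191 on the autosomes, and 1 knockdown peak. The share of genes with a knockdown peak also rose with gene length, where a longer gene has more room for a peak. Marked genes up to 5 kb kept a knockdown peak in 23 of 556 cases (4.14%, 2.64 to 6.14) and those above 200 kb in 102 of 380 (26.8%, 22.5 to 31.6), while knockdown-covered as a share of control-covered sequence fell from 3.33% below 5 kb to 1.99% at 50 to 100 kb and was 5.22% above 200 kb.

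Peaks were 10.1 times fewer after knockdown, and the knockdown ChIP was also sequenced less deeply. Thinning the tags of each control peak to the knockdown depth left 27682 control peaks (90.4%) past the caller's threshold, 9.11 times the knockdown number, which argues against depth as the whole cause. Among peaks of 8 kb or shorter the ratio was 9.29, which decides nothing about the caller on long domains, since dropping them would mainly shorten the control list. Loss of the mark with Setd2, the difference the design names, stays open as a hypothesis. Differences in ChIP efficiency between the conditions were not tested, as no spike-in values were analysed here. Only knockdown cells received doxycycline, so an effect of doxycycline itself cannot be told apart from that of the knockdown.

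In 128 genes a knockdown peak stood without a control peak, and 101 of them had no control-covered base pair. A candidate explanation is that the caller dropped long control domains, because the background implied by its scores rose from 1.06 to 2.74 times the genome mean between peaks up to 8 kb and above 20 kb. Among the 319 members of 11 lists of broadly used genes (ribosome to DNA repair), 5 of 85 of 20 to 70 kb (5.88%, 1.94 to 13.2) had no control-covered base pair, against 6 of 121 of 5 to 20 kb (4.96%, 1.84 to 10.5) and 12 of 96 below 5 kb (12.5%), and without 8 tissue-restricted members such as Psma8 these were 4 of 84, 4 of 119 and 8 of 91. The shorter classes included Pgk1, Psmd10, Rpl39, Rpl36a, Rpl10, Ndufa1 and Ndufb11 on the X chromosome, which had few control peaks. Their shares are thus a loose yardstick for the longer genes. Of the uncovered members only Psma8, Sf3b3, Top2a and Cct3, all of 20 to 70 kb, had a knockdown peak, where a longer gene has more room for one. These counts are too few to decide, so the cases cannot be told apart from a lost domain. For the 121 of the 128 genes outside the 11 lists, knockdown peaks had a median score of 66.0 against 78.5 in genes with both peaks. Chance peaks near the threshold would lower the median, but so would other weak peaks, so it cannot decide between them. The median also says nothing about single genes such as Dync1h1, which had 3 knockdown peaks over 6512 bp.

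The Zfp genes may keep a peak for a reason other than their control-covered share. Their kept share of 21.0% lay above the bound that only the highest 2.5% of random lists matched on that share exceed (12.5%). Those lists were not matched on gene length or tags per kb. The kept share of all marked genes rose from 4.14% up to 5 kb to 26.8% above 200 kb. The overlapped share of genic control peaks rose from 0.665% in the sparsest decile of tags per kb to 21.7% in the densest. The repeated cluster of chromosome 4 does not account for the high kept share of Zfp genes. Elsewhere 43 of 236 Zfp genes (18.2%, 13.5 to 23.7) kept a peak against a bound of 12.7%. Reads shared between neighbouring copies remain possible. Zfp genes with no other within 500 kb kept a peak in 14 of 85 cases (16.5%, 9.31 to 26.1), equal to the random bound of 16.5%, and those with such a neighbour in 40 of 172 (23.3%, 17.2 to 30.3), so this explanation cannot be told apart from retention at these numbers. Retained trimethylation at zinc finger clusters is therefore only a hypothesis.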
